A study of Mus musculus with 6 samples.

How the data were processed

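Total RNA of hearts at postnatal day 10 was extracted with Trizol, amplified and labelled with biotin, per the labels' protocols. The RNA was hybridised to Affymetrix mouse expression arrays with 45101 probe sets. Scanner software was GCOS 1.4, per the submitters' processing notes. The deposited values are log2 expression values that the authors made with RMA in the affy package of R and Bioconductor, per the series' design text. RMA corrects background, normalizes quantiles between arrays and summarises the probes of a probe set. The versions of R and affy used by the authors are not given in the sources used here. Every value lay between 2.64 and 14.6, and no array was a copy of another: correlations between arrays ran from 0.991 to 0.997, and 0 pairs of arrays were identical. RMA compresses differences near the bottom of its scale, and forcing all arrays to one distribution removes any change shared by most genes. Arrays carry no read depth, and signal near the floor of about 2.7 is background.

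Samples were grouped by their titles into 2 genotypes, wild type and knockout, with 3 hearts each. The series' design text gives 3 mice per genotype, so arrays were treated as separate animals. Litter, strain and sex were not given in the sources used here.

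The 64 control probe sets were left out, which left 45037. Probe sets were named through the platform annotation with symbols updated by gene identifier through the RefSeq table of GRCm38.p6. Of the 45037 probe sets, 34945 named 1 gene, 932 several and 9160 none. A gene was represented by its probe set with the highest mean over the 6 arrays, taken only from probe sets that name 1 gene, which gave 18193 genes. Of these, 18032 were matched to the reference by identifier. The table was also used to find genes near Mib1 (18031 genes had a position), and its coordinates are not printed because the build behind the array annotation is not stated. Named genes with several probe sets were checked for agreement: of 34 such genes, 24 had all probe sets in one direction. In the others (E2f1, Hand2, Hdac4, Jph2, Kcnd2, Kif2a, Myh6, Nr2f2, Pfkl and Ppp2r5a) at least 1 dimmer probe set went the opposite way.

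Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all genes or probe sets and a threshold of 0.05. The 2 groups were compared without a block. Gene lists were fixed before the data were examined: 29 lists of 746 different genes in all, of which 673 were measured. Lists were written by hand from general knowledge, some share genes, and a few list entries were matched through older symbols. Irx4, Irx5 and Kcnd2 were listed knowing that the study group had examined them in these mice. Hand2 was listed knowing that the group had worked on it. A pass of these genes over a list alone, or their part in a list's call, is therefore not independent of that earlier work. Each list was tested with camera from limma against all other genes, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests a list without reference to other genes. Genes near the targeted locus were tested with Fisher's exact test, two-sided. The tests, the gene lists and the naming rule were chosen before the data were examined.

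The naming rule took the 10 largest rises and 10 largest falls among genes that passed with the groups apart, filled up to 10 in each direction by the smallest unadjusted p, leaving out clone names and predicted symbols. It also took up to 4 members of each list with the smallest p, of which a part is named, and always Mib1, Hand2, Irx4, Irx5, Kcnd2, Hdac4, Gja1, Nppa, Nppb, Myh6, Myh7 and Acta1. Genes that passed with the replicate block were named as well.

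Wild-type and knockout samples share the replicate numbers 1, 2 and 3 in their titles, with no statement that a number marks a litter or a day. The numbers were therefore checked on the data. Across genes, the deviations of same-numbered arrays from their group means correlated at 0.54 for replicate 1, 0.18 for replicate 2 and 0.13 for replicate 3. All 3 lie above 0.1, which was the condition set for treating the numbers as pairs before the fits were compared. Deviations from a group mean sum to 0, so the shared deviation of replicate 1 by itself raises the correlations among replicates 2 and 3. Passing 0.1 is thus no evidence of pairing for replicates 2 and 3. The crossed pairs correlated more: wild-type replicate 2 at 0.35 with knockout replicate 3, and wild-type replicate 3 at 0.30 with knockout replicate 2. Only the pairing of replicate 1 has a basis in the data, and that of replicates 2 and 3 rests on the titles alone. Genes are not independent replicates in these correlations.

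The steps were tested on simulated data drawn around the real means of the 18193 genes, with real replicate-number deviations and 200 genes changed by known folds. Without the block, 73.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold were recovered, with 0 of 17993 unchanged genes called. With the block, 100% at each fold were recovered and 11 unchanged genes were called. The simulated noise is independent between genes, which real arrays are not. The simulation also gave both arrays of a number the same deviation and took its noise from the blocked fit. The gain from the block was therefore built in, and it does not show that the real arrays are paired.

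Alternatives covered the replicate block, leaving out each array, a further quantile normalization, centring on array medians, leaving out dim probe sets, the mean of all probe sets of a gene, leaving out probe sets open to cross-hybridisation, a variance trend with robust estimation, array weights, other thresholds and other windows around the locus. After the data were examined, other fits were added. They took the first replicates as a batch, replicates 2 and 3 only, or the Xist level, high or low, as a covariate. Others took the block without each replicate number, or one unadjusted criterion for genes near the locus. All wild-type arrays but only knockout replicate 2 of the knockouts have high Xist. The genotype difference with the Xist covariate is therefore that 1 knockout array against the wild-type mean, and every call in that fit rests on it. A planned test of genes with a miR-1 site in the 3′ untranslated region needs transcript sequence, which was not used here, and it was not run.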

Results

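The series measured messenger RNA in whole hearts of mice at postnatal day 10, in 3 wild-type mice and 3 mice lacking miR-1-2. miR-1-2 is one of the genes that make miR-1, a microRNA of heart and skeletal muscle. MicroRNAs lower the messenger RNAs they pair with, so the comparison asks which heart transcripts were higher or lower without this gene. Each mouse was measured on 1 array. The 6 arrays carried 45037 probe sets that were tested, and 18193 genes were represented by 1 probe set each. Array medians lay between 6.03 and 6.11 on the log2 scale. With 3 arrays per group, the number of arrays limits the precision of every value.

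The microRNA itself was not analysed here, so the genotype labels could not be checked on the targeted gene. Its host gene is Mib1, a ubiquitin ligase of Notch signalling. Mib1 was at 8.30 ± 0.11 (SD, n = 3) in wild type and 7.97 ± 0.35 in knockout, a log2 difference of -0.33 that did not pass (adjusted p = 1.00). Knockout replicate 1 stood at 7.56 and the other knockout arrays at 8.15 and 8.19. The other Mib1 probe sets differed by -0.13 and -0.040. A probe set outside a deleted part does not check a deletion.

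The arrays differed in ways other than the genotype. Xist, the RNA of the inactive X chromosome, was high in all 3 wild-type arrays (11.91, 12.13 and 12.08) and in knockout replicate 2 (12.19), and low in knockout replicates 1 and 3 (7.55 and 7.57). Eif2s3y, on the Y chromosome, was at 7.63 and 8.35 in those low-Xist arrays and between 2.85 and 3.16 in the others. Sex was thus not balanced between the groups. Every fit without knockout replicate 2 sets low-Xist knockout against high-Xist wild-type arrays, so sex and genotype coincide in it, for lists as for genes. Ucp1, the uncoupling protein of brown fat, was at 9.45 and 10.39 in replicate 1 of wild type and knockout and between 5.22 and 6.68 in the other arrays. The first principal component held 50.1% of the variance and placed both first replicates at one end.

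**Figure D1:**
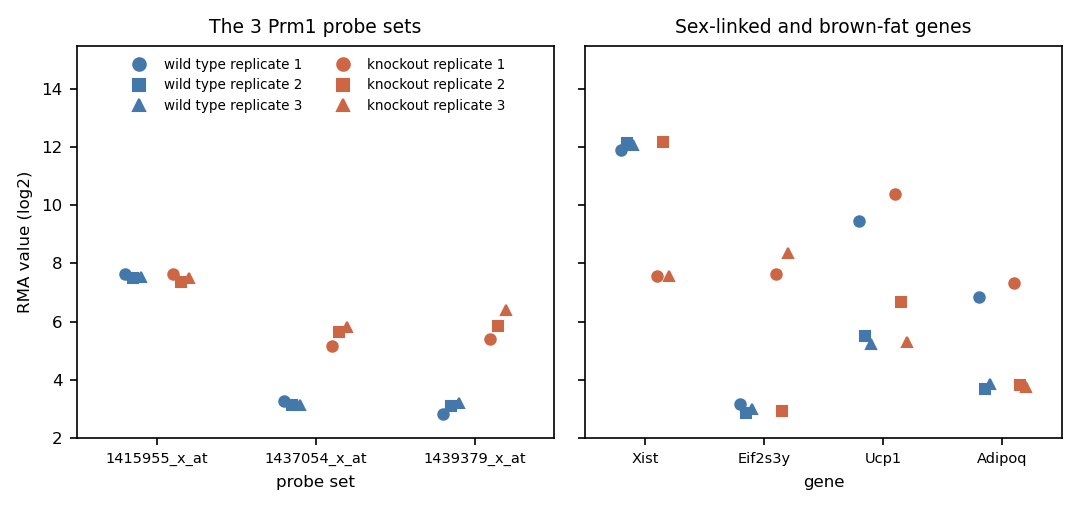
RMA values (log2) on each of the 6 arrays, with wild type in blue and knockout in red and 1 marker shape per replicate number. Left, the 3 probe sets of Prm1, of which 1 lay near 7.5 in both groups and 2 were higher in every knockout array; right, Xist, Eif2s3y, Ucp1 and Adipoq, which separate low-Xist arrays and both first replicates from the rest.

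Between the 2 groups as such, 3 probe sets passed the adjusted threshold, a pair from the protamine gene Prm1 and 1 from Cox6a1, and 0 genes did. With the replicate number as a block 13 genes passed, among them the 6 given here. Myh7, the slow myosin heavy chain of fetal ventricle, was 2.99-fold higher in knockout, at 10.64 ± 1.12 (SD, n = 3) against 9.06 ± 0.76, and the values of the groups overlapped. Kcnd2, a pore subunit of the transient outward potassium current, was 1.83-fold lower, at 6.48 ± 0.29 against 7.35 ± 0.22. Trim54, a sarcomere-associated ubiquitin ligase, was 1.96-fold lower and Hamp, which encodes the iron hormone hepcidin, 1.74-fold lower. Bex4 was 2.24-fold higher, and Cox8a, a subunit of cytochrome c oxidase, was 1.45-fold higher at 11.80 ± 0.03 against 11.26 ± 0.04.

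None of these 6 genes passed over all genes when the groups were compared without regard to the replicate numbers (adjusted p = 1.00 for Myh7). In that fit, with limma, 0 of 18193 genes reached an adjusted p of 0.05. The smallest adjusted p was 0.334, for Cox8a and Trim54, and 746 genes had an unadjusted p under 0.05. With the replicate number as a block 1326 did. Chance gives 910 where arrays share no deviations. In simulated data built to carry the replicate-number deviations, 129 of 17993 unchanged genes had an unadjusted p under 0.05 without the block and 888 with it. That gap follows from how the data were simulated. Where arrays do share deviations, 746 cannot be read as below chance. Knockout and wild-type values did not overlap for 1611 genes, 8.86% of them, where chance gives 10% for exchangeable arrays, which these are not.

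With the replicate number as a block, so that each knockout array was compared with the wild-type array of its number, 13 genes passed. Of these, 8 rose and 5 fell. The rises were Myh7 (log2 1.58, adjusted p = 0.0261), Bex4 (1.16), Ptgds (0.78), Cubn (0.70), Slc25a23 (0.70), Efnb3 (0.66), Aldh1b1 (0.61) and Cox8a (0.54). The falls were Trim54 (-0.97), Kcnd2 (-0.87, adjusted p = 0.0318), Hamp (-0.80), Asb5 (-0.78) and Art1 (-0.56). All 13 differed in the same direction in all 3 pairs, which a pick by the blocked fit favours. Without the pair of replicate 1, 7 genes passed in the blocked fit. Without replicate 2 the blocked fit gave 36, and without replicate 3 it gave 0. The arrays left without replicate 2 are high-Xist wild type and low-Xist knockout, so sex and genotype cannot be separated in that fit, and Xist and Eif2s3y are among its 36 genes.

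**Figure D2:**
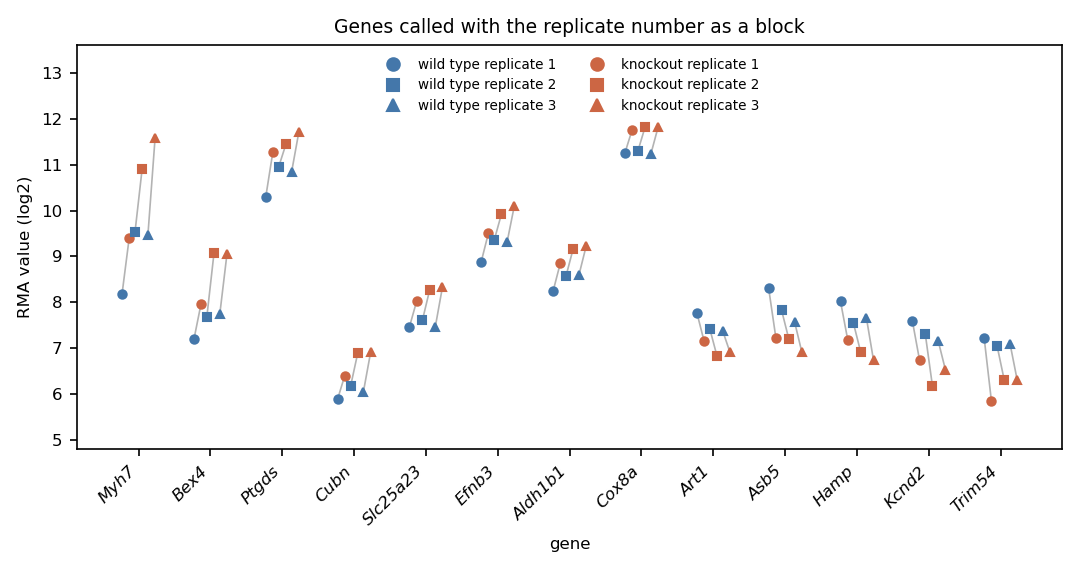
RMA values (log2) of the 13 genes that passed with the replicate number as a block, on each of the 6 arrays (blue wild type, red knockout). Grey lines join arrays of the same replicate number, and all lines of a gene run the same way, upward for the 8 genes at the left and downward for the 5 at the right.

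The named-gene rule also took genes that passed neither fit over all genes, and only their values are given. Among those higher in knockout were Cox6a1 (log2 0.51 ± 0.07, SE), Mov10l1 (0.42), Hlf (0.38), Khdrbs3 (0.38), Ftcd (0.39), Pgam1 (0.40), Prps2 (0.45) and Cadm4 (0.47). Among those lower were Acss1 (-0.48 ± 0.08), a mitochondrial acetyl-CoA synthetase, and Asb14 (-0.46), Iigp1 (-0.47), Mybpc2 (-0.38), Lrrc3b (-0.44), Arhgap20 (-0.38) and Apon (-0.33). Their adjusted p-values lay between 0.373 for Cox6a1 and 0.722 for Apon without the block.

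At the level of single probe sets, 3 of 45037 passed without the block, and all were higher in knockout. A pair of them belonged to Prm1, a protamine that packs DNA in sperm, with log2 differences of 2.36 and 2.85 and adjusted p-values of 0.00247 and 0.0063. They stood at 3.17 and 3.04 in wild type, near the bottom of the scale. The brightest Prm1 probe set, which stood for the gene, differed by -0.077. The other was a Cox6a1 probe set (0.77). The count was 1 without each wild-type array in turn, 6 without knockout replicate 1, 15 without knockout replicate 2, where sex and genotype again coincide, and 2 without knockout replicate 3. With the replicate number as a block 20 probe sets passed, 11 higher and 9 lower, the Prm1 pair among them. One of these was an Art1 probe set at -2.20, beside -0.56 for the one that stood for Art1, an ADP-ribosyltransferase of muscle. Another was an Arhgap20 probe set at -1.11, beside -0.38 for the one that stood for Arhgap20.

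Of 32 measured genes of cardiac conduction and potassium channels, 18 were higher and 14 lower in knockout. Over all genes, 0 passed without the block and 1, Kcnd2, with it. Adjusted over the list alone, 3 passed without the block: Irx5 rose (7.33 ± 0.12 against 6.93 ± 0.12, n = 3), Kcnip2 rose (log2 0.52) and Kcnd2 fell. Irx5 is a homeobox factor that represses Kcnd2, and Kcnip2 encodes a partner subunit of the channel. With the block, 9 passed over the list alone, 8 higher and 1 lower. Irx4, the ventricular member of the Irx family, was 0.43 higher, and Gja1, the main gap junction protein of ventricle, was 0.20 higher. Gja1 stood at 12.52 in wild-type replicate 1 against 12.84 and 12.82 in the other wild-type arrays, and its groups overlapped. As a set the list did not pass without the block (camera adjusted p = 0.0559) and passed with it (adjusted p = 0.018, and adjusted p = 0.747 with an estimated correlation). The list was called upward in 10 of 24 alternatives, among them the fits without knockout replicate 1 (adjusted p = 0.0279), without wild-type replicate 2 (0.0434) and without wild-type replicate 3 (0.0182), over a range of adjusted p from 0.0166 to 0.949.

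Cardiac transcription factors were called as a set. Of 39 measured, 28 were higher in knockout, with a median log2 difference of 0.099 (camera adjusted p = 1.6e-04 with a preset correlation, and adjusted p = 0.928 with an estimated correlation). The mean difference of 0.12 was 0.072 without wild-type replicate 1 (adjusted p = 0.0112), 0.075 without knockout replicate 2 (0.0392) and 0.18 without knockout replicate 1 (1.2e-04). Over all genes 0 passed, and adjusted over the list alone 0 passed without the block and 9 with it. Irx5, Irx4, Irx3 (log2 0.36 ± 0.11, SE) and Hand2 were among these 9, and Hopx (0.18 ± 0.06) was not. The others were Gata6, Hey2, Hdac9, Tbx2 and Tbx20, and Gata6 lies within 20 Mb of Mib1. Hand2, a basic helix-loop-helix factor and a reported target of miR-1, was at 9.12 ± 0.33 (SD, n = 3) against 8.78 ± 0.25, a difference of 0.35 that did not pass over all genes (adjusted p = 1.00, and 0.338 with the replicate number as a block). It was higher in 3 of 3 pairs.

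Whether transcripts reported as miR-1 targets were called as a set depended on the setting. Of 34 measured, 24 were higher in knockout, with a median of 0.031 and a mean of 0.056, which missed the threshold (camera adjusted p = 0.0607, and 0.0519 with the block). The list was called upward in 10 of 24 alternatives. These included the fits without knockout replicate 1 (mean 0.12, adjusted p = 0.00212), without wild-type replicate 2 (0.069, adjusted p = 0.042), without wild-type replicate 3 (0.074, adjusted p = 0.0338) and with replicates 2 and 3 only (0.087, adjusted p = 0.00886). The others were the fits without ambiguous probe sets, with trend and robust variance, with array weights, with the first replicates as a batch, with the Xist level as a covariate and with the block without replicate 1. The list was not called without knockout replicate 2, knockout replicate 3 or wild-type replicate 1. Leaving out any of these arrays lowered the mean difference. The list's mean was highest in knockout replicate 2 (9.21) and, among wild-type arrays, lowest in replicate 1 (9.003). With an estimated correlation the adjusted p was 0.964, the highest of the 24. Over all genes and adjusted over the list alone 0 passed, with and without the block. The members with the smallest p besides Hand2 were Ppp2r5a (0.30), Kif2a (0.23) and Slc8a1 (0.16). Another Ppp2r5a probe set differed by -0.13. Hdac4, a reported target, differed by 0.16 (adjusted p = 1.00), and its other probe sets went the opposite way.

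Sarcomere genes and the fetal and stress genes went both ways. Of 31 sarcomere genes 17 were higher, with a median of 0.0084 (camera adjusted p = 0.721), and of 17 fetal and stress genes 7 were higher, with a median of -0.038 (adjusted p = 0.985). The fetal and stress list was called upward with the Xist covariate (adjusted p = 0.029) and downward with the block without replicate 2 (0.0094). Without the block, Acta1 and Nmrk2 passed adjusted over the fetal and stress list alone, and no sarcomere gene did. Acta1, skeletal actin, fell by 0.53 and Nmrk2, a kinase of NAD synthesis, rose by 0.29. With the block, 3 sarcomere genes and 6 fetal and stress genes passed over their lists alone. Tnni1, the slow fetal troponin I, singled out after its values were seen, was 0.85 higher in knockout and passed over the lists alone with the block (adjusted p over all genes = 0.109 in that fit). Much of that difference comes from wild-type replicate 1, where Tnni1 stood at 10.49 against 12.23 and 12.14 in the other wild-type arrays. Nppb, the stress-induced natriuretic peptide, was 0.72 lower in knockout (adjusted p = 0.0837 with the block), Nppa 0.45 lower and Csrp3 0.23 lower. Without knockout replicate 1 Nppb differed by -0.36. Nppa was higher in 1 of 3 pairs and differed by -0.054 without knockout replicate 3. Myh6, the fast myosin of adult ventricle, was at 14.34 ± 0.05 against 14.33 ± 0.01, and its other probe set differed by -0.39. The brighter probe set lies near the highest values on the arrays (14.50 to 14.59), where a change may not show.

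Calcium-handling genes were not called by camera (12 of 21 higher, median 0.0017, camera adjusted p = 0.425), and passed with fry in either direction with the block (adjusted p = 0.0452), a test that the conduction and cardiac transcription factor lists passed too (0.0452 for both). Adjusted over the list alone, Sri, encoding the calcium-binding protein sorcin, rose by 0.39 without the block and with it. Hrc differed by -0.24 and Jph2 by 0.23.

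The metabolic lists were not called by camera in the default fit or with the block, and some were called in other settings. Of 27 fatty acid oxidation genes 10 were higher (median -0.024, camera adjusted p = 0.395), and fry in either direction passed with the block (adjusted p = 0.0458). Pdk4, the kinase that shuts off pyruvate dehydrogenase, was 0.72 lower in knockout at 10.87 ± 0.14 against 11.59 ± 0.42 (SD, n = 3) and passed over the list alone with the block. Cpt1a was 0.26 higher. Of 19 glycolysis genes 12 were higher (median 0.029, adjusted p = 0.0559), and the list was called upward in 6 of 24 alternatives. These were the fits without knockout replicate 2 (adjusted p = 0.0227), without wild-type replicate 2 (0.0214), without ambiguous probe sets (0.0456), with trend and robust variance (0.0453), with array weights (0.017) and with the block without replicate 2 (0.0061). In the first and last of these fits sex and genotype coincide. Pgam1 rose over the list alone without the block, and Pfkl (0.34) rose over the list alone with it, while Hk2 differed by -0.23. Of 43 oxidative phosphorylation genes 15 were higher (median -0.016, adjusted p = 0.395), and the list was called downward with the Xist level as a covariate (adjusted p = 0.0055) and with the block without replicate 3 (0.0285). The lowest was Cox7a1 (-0.22), the heart and muscle isoform, in contrast to Cox8a and Cox6a1 above.

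Myeloid markers and lymphoid and thymus markers were called as lower in the knockout arrays by camera with a preset correlation only. Of 29 myeloid markers 23 were lower, with a median of -0.13 and a mean of -0.14 (camera adjusted p = 6.9e-06, and adjusted p = 0.928 with an estimated correlation). Without wild-type replicate 1 the mean was -0.073 (adjusted p = 0.0055). Examples are Cd68 (-0.32), Mrc1 (-0.44), Adgre1 (-0.25) and Ctss (-0.23). Over all genes 0 passed, and adjusted over the list alone 0 passed without the block and 9, all lower, with it. Lymphoid and thymus markers were lower in 18 of 23 (median -0.084, camera adjusted p = 0.0223, and adjusted p = 0.928 with an estimated correlation), and 0 passed over the list alone. The call was lost with a further quantile normalization (mean -0.087, adjusted p = 0.122) and with the mean of probe sets per gene (-0.095, adjusted p = 0.105). Their mean was highest in replicate 1 of both groups, at 5.97 in wild type and 5.85 in knockout, against 5.64 to 5.76 elsewhere. With the block the lymphoid and thymus list was called too (camera adjusted p = 0.0024 with a preset correlation, and 0.747 with an estimated correlation). Without the block, leaving out wild-type replicate 1 gave a mean difference of -0.021 (adjusted p = 0.447). The mean was -0.10 with all arrays, -0.17 without knockout replicate 1 (adjusted p = 0.00212) and -0.15 without wild-type replicate 2 (adjusted p = 9.9e-04). It was -0.068 without knockout replicate 2 (adjusted p = 0.266) and -0.067 without knockout replicate 3 (adjusted p = 0.168).

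Atrial genes were lower in 14 of 15 cases, with a median of -0.27 and a mean of -0.33 (camera adjusted p = 2.9e-05, and adjusted p = 0.928 with an estimated correlation). Hamp passed over the list alone. Bmp10 differed by -0.27 and Nr2f2 by -0.18. Nppa, the atrial natriuretic peptide, and Stard10 were lowest in knockout replicate 3, at 12.16 and 7.54, and next lowest in wild-type replicate 2, at 13.09 and 8.39. Without knockout replicate 3 they differed by -0.054 and -0.14. The list's mean was 8.14 in knockout replicate 3, 8.65 in wild-type replicate 2 and between 8.72 and 9.12 in the other arrays. Without knockout replicate 3, the mean difference was -0.11 (adjusted p = 0.0779). Without knockout replicate 2, where sex and genotype coincide, it was -0.51 (adjusted p = 3.7e-11). With the Xist level as a covariate it was 0.031, which is knockout replicate 2 alone against the wild-type mean.

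**Figure D3:**
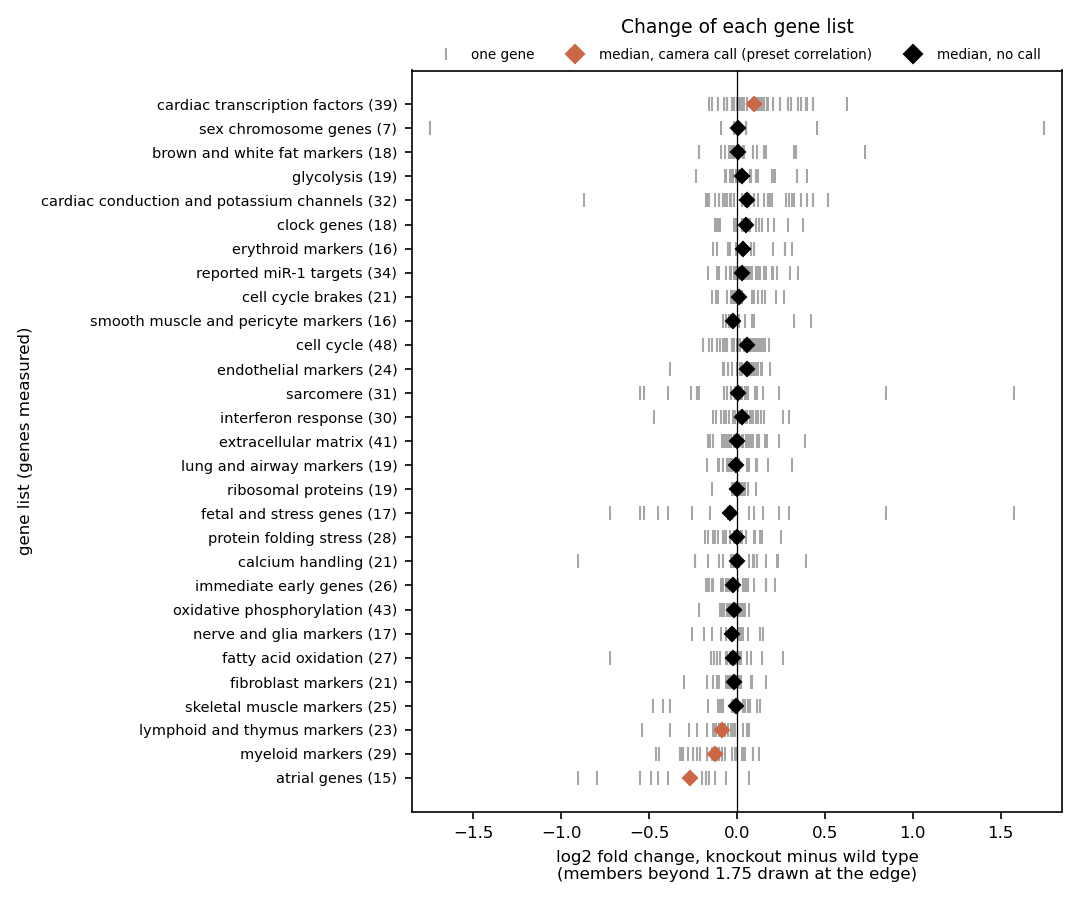
Log2 fold change (knockout minus wild type) of each gene in the 29 lists, as grey ticks, with each list's median as a diamond. The 4 lists called by camera with a preset correlation are in red; atrial genes have the lowest median (-0.27) and cardiac transcription factors the highest (0.099).

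The lists of the remaining cell types were not called by camera in the default fit or with the block, and some were called in other settings. Fibroblast markers were higher in 6 of 21 (median -0.018, camera adjusted p = 0.34), with Thy1 at -0.17. They were called downward without knockout replicate 2 (adjusted p = 3.9e-04), without wild-type replicate 2 (0.0016), with array weights (0.030) and with the block without replicate 2 (2.8e-10). Sex and genotype coincide in the first and last of these fits. The array weights rest largely on knockout replicate 3, which has low Xist. Endothelial markers were higher in 18 of 24 (0.059, adjusted p = 0.411), with Lyve1, of lymphatic vessels and some macrophages, at -0.38 and Aqp1 at 0.19, and were called upward with the Xist level as a covariate (adjusted p = 0.0219). Smooth muscle and pericyte markers were higher in 7 of 16 (-0.025, adjusted p = 0.623), and Acta2, smooth muscle actin, rose by 0.42 adjusted over the list alone, as did Cnn1 (0.32) with the block. This list was also called upward with the Xist covariate (adjusted p = 0.0317). Erythroid markers were higher in 9 of 16 (0.036, adjusted p = 0.425), with Rhd at 0.27. Skeletal muscle markers were higher in 11 of 25 (-0.0085, adjusted p = 0.395), and Mybpc2 and Neb fell over the list alone, by 0.38 and 0.48. Neb stood at 3.68 in wild type and 3.20 in knockout, near the bottom of the scale, so its fall cannot be told from background. Brown and white fat markers were higher in 9 of 18 (0.0083, adjusted p = 0.658). Their mean was 7.70 and 7.82 in both first replicates and between 6.99 and 7.12 elsewhere, and Fasn (0.33), Cidea (0.34) and Ucp1 (0.73) passed over the list alone with the block. Ucp1 differed by -0.74 without knockout replicate 1 and by -0.021 without wild-type replicate 3. The list passed with fry in either direction with the block (adjusted p = 0.0452) and was called upward by camera without wild-type replicate 1 (adjusted p = 0.0164) and with the block without replicate 3 (0.0381). Lung and airway markers were higher in 9 of 19 (-0.0041, adjusted p = 0.985) and nerve and glia markers in 7 of 17 (-0.027, adjusted p = 0.49), with Gap43 at -0.25.

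Of the general programmes, the cell cycle was higher in 33 of 48 genes (median 0.057, camera adjusted p = 0.395), with Gmnn at 0.14 and E2f1 at -0.14. It was called upward in 6 of 24 alternatives, among them the fits without knockout replicate 1 (adjusted p = 2.1e-04) and without wild-type replicate 3 (0.0043) and with the Xist covariate. Without knockout replicate 2, knockout replicate 3 or wild-type replicate 1 the list was not called, and its mean difference turned negative. Cell cycle brakes were higher in 13 of 21 (0.011, adjusted p = 0.411), with Cdkn2a at 0.22, and were called upward with the Xist covariate (adjusted p = 0.0352). Extracellular matrix genes were higher in 21 of 41 (0.0018, adjusted p = 0.514), with Timp1 at 0.24. They were called upward without knockout replicate 1 (adjusted p = 0.0279) and without knockout replicate 3 (0.048), and downward without knockout replicate 2 (3.9e-04), where sex and genotype coincide. In all they were called in 7 of 24 alternatives, 5 upward and 2 downward. Interferon response genes were higher in 19 of 30 (0.028, adjusted p = 0.405), and Iigp1, an interferon-induced GTPase, fell over the list alone by 0.47. Without wild-type replicate 1 the list was called upward (adjusted p = 0.0157), and it passed with fry in either direction with the block (adjusted p = 0.0452). Clock genes were higher in 11 of 18 (0.053, adjusted p = 0.15), and Hlf, a clock output factor, rose over the list alone by 0.38. The clock list was called upward without knockout replicate 1 (adjusted p = 0.0436) and without wild-type replicate 3 (0.0285). Immediate early genes were higher in 11 of 26 (-0.024, adjusted p = 0.49), with Hspa1b at -0.16, and were called downward without wild-type replicate 1 (adjusted p = 0.0055). Protein folding stress genes were higher in 14 of 28 (5e-05, adjusted p = 0.883), with Hspb1 at 0.14. Ribosomal protein genes were higher in 11 of 19 (0.0017, adjusted p = 0.801), with Rps16 at -0.14 but at a mean level of 3.83, near the bottom of the scale. Sex chromosome genes were higher in 4 of 7 (0.008, adjusted p = 0.778), and 3 of them, Xist and Eif2s3y included, passed over the list alone with the block.

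Whether genes near the targeted locus on chromosome 18 were over-represented depended on the fit. Mib1 has 95 measured genes within 20 Mb. Fisher's exact test counts genes as independent, but all were measured on the same mice and may vary together. Its p-values here therefore do not measure variation between animals. Fewer than 10 genes passed without the block, so an unadjusted p under 0.01 was used, and 1 of these 95 genes (1.05%) met it, against 158 of 17936 elsewhere (0.881%), an odds ratio of 1.20 (two-sided Fisher's exact test p = 0.57). With the replicate number as a block and the same unadjusted criterion, 6 of the 95 genes, Mib1 among them, met it, against 334 of 17936 elsewhere, an odds ratio of 3.55 (exact p = 0.0092). Leaving out a replicate number from the blocked fit gave odds ratios of 3.49 without replicate 1 (exact p = 0.0019), 1.49 without replicate 2 (exact p = 0.461) and 4.88 without replicate 3 (exact p = 0.0267). With the first replicates as a batch it was 2.48 (exact p = 0.0413). Without the block, the odds ratio was 2.29 without knockout replicate 1 (exact p = 0.0266) and 2.34 without wild-type replicate 1 (exact p = 0.352), and without each of the 4 other arrays in turn 0 of the 95 genes met the criterion (exact p = 1.00). With replicates 2 and 3 only it was 3.02 (exact p = 0.0048), and with the Xist level as a covariate 1.72 (exact p = 0.329).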

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

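The settings with the first replicates as a batch, with replicates 2 and 3 only, with the Xist level as a covariate, with the block without one replicate number, with an estimated correlation plus the block, and with an unadjusted criterion near the locus where 10 or more genes passed were chosen after seeing the data. The planned test of miR-1 sites and its alternatives were not run for lack of sequence.

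The count of genes, 0 by default (746 at an unadjusted p under 0.05), stayed at 0 with a further quantile normalization, array medians centred, dim probe sets left out, ambiguous probe sets left out, trend and robust variance, a threshold of 0.1, a 1.5-fold minimum, no variance sharing and the Xist covariate. It was 13 with the replicate block, 3 with the mean of probe sets per gene (Prm1, Cox6a1 and Arhgap20, not among the 13), 416 with array weights, 15 with the first replicates as a batch and 1 with replicates 2 and 3 only. Leaving out single arrays gave 0 to 4 genes (4 without knockout replicate 1, 2 without knockout replicate 2), and leaving out a replicate number with the replicate block gave 0 to 36. The array weights ran from 0.222 for knockout replicate 1 to 4.74 for knockout replicate 3, so that fit rests largely on 1 knockout array. The 13 block genes kept their sign in all settings run, which their selection favours. Not independently of it, the batch fit called 12 and array weights all 13.

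The count of probe sets, 3 by default, was 20 with the replicate block, 0 without dim probe sets, 0 without ambiguous probe sets, 6 with trend and robust variance, 24 with array weights, 24 with the first replicates as a batch and 0 with the Xist covariate. It ran from 1 to 15 without single arrays and from 3 to 55 with the replicate block without one number. The suffixes of all 3 default probe sets mark shared probes, so the ambiguity filter removes them. The brightness limit removes the Prm1 pair alone, and Cox6a1 lost its call. Other causes were not tested.

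The count of gene lists, 4 by default and 5 with the replicate block, was 0 with an estimated correlation (0 also with the replicate block), 0 with fry in one direction and 0 in either direction, where the smallest adjusted p were 0.928, 0.949 and 0.121. With the replicate block, fry in either direction called 6 lists. It was 7 with trend and robust variance, 8 with array weights, 7 with replicates 2 and 3 only and 11 with the Xist covariate, 3 to 9 without single arrays and 7 to 8 with the replicate block without one number. Cardiac transcription factors and myeloid markers were called by camera without each single array (adjusted p from 6e-05 to 0.0392 and from 1.6e-09 to 0.0055). These fits kept the preset correlation of 0.01, while the estimates on all arrays were 0.16 and 0.39. Where the genes of a list vary together, such p-values are too small, so these calls do not show stability between mice. The mean of atrial genes turned from -0.33 to 0.031 with the Xist covariate, a fit that sets knockout replicate 2 alone against the wild type.

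The odds ratio near the locus, at an unadjusted p under 0.01, was 1.20 by default, 3.55 with the replicate block, 2.48 with the first replicates as a batch, 3.02 with replicates 2 and 3 only, 1.30 with array weights, 0 to 2.34 without single arrays and 1.49 to 4.88 with the replicate block without one number (3.49 without replicate 1). Where 10 or more genes passed, the rule was the stricter adjusted threshold. By it the ratio was 1.89 with array weights (4 of 95 genes), 0 with the replicate block, 0 with the first replicates as a batch and 0 with the replicate block without replicate 2; the fits at 0 called 13 to 36 genes elsewhere, too few for a 0 to say anything. Over 82 named genes and 1632 values under alternatives, 1511 kept their direction and their side of the threshold, 109 newly passed and 12 changed sign. Ucp1 turned to -0.53 with array weights, to -0.039 with the Xist covariate, to -0.74 without knockout replicate 1 and to -0.021 without wild-type replicate 3 (2.09 without wild-type replicate 1). Myh6 turned to -0.19 with the mean of probe sets, to -0.014 without knockout replicate 3 (0.035 without knockout replicate 1), to -0.0072 with the Xist covariate and to -0.012 with the replicate block without replicate 3; with the Xist covariate Nppa turned to 0.024, Stard10 to 0.031, Eif2s3y to -0.088 and Xist to 0.15, the last by construction. Beyond these and the counts over single lists, the replicate block changed no other call. Probe sets near background limit what can be read for the Prm1 pair, Neb and Rps16.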

Other observations

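The tests of sex, of knockout replicate 3 and of the disagreement between Prm1 probe sets, and the counts of splits for genes and probe sets without the block, were chosen after the results they measure had been seen.

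Replicate 1 of both groups shared differences from the other arrays that the genotype comparison does not describe. Besides Ucp1, Adipoq, the fat hormone adiponectin, was at 6.85 and 7.32 in wild-type and knockout replicate 1 and between 3.68 and 3.86 in the other arrays. Car3 was higher by 1.97 on average, Thrsp by 1.54 and Rag1, a recombinase of developing lymphocytes, by 1.38. In wild-type replicate 1 Rag1 stood at 5.90. Myh7 (-1.58), Tnni1 (-1.34), Hey2 (-0.91) and Nppb (-0.90) were lower there. The mean of 25 genes high in the newborn heart was 8.94 and 8.92 in the first replicates and between 9.10 and 9.26 in the others, and that of 19 genes high in the adult heart was 9.99 and 9.94 against 9.97 to 10.03. Over all 18193 genes 9 were higher and 4 lower by over 1 on the log2 scale, picked by size with no test. Both first replicates lay beyond the 4 other arrays for 8 of the 9 and 3 of the 4; the exceptions, Eif2s3y and Xist, follow the low Xist of knockout replicate 1 and are not shared.

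Among the Prm1 probe sets, a pair was higher in every knockout array. The 26 other spermatid genes measured had a median difference of -0.025 (quartiles -0.071 and 0.031), which argues against testis or germ cell RNA in the knockout samples, since that would raise them all; Tnp1 and Prm2, abundant in spermatids, differed by 0.076 and -0.027. Sex stays open: the knockout array with high Xist stood 2.47 and 2.82 above the wild-type mean, which goes against a sex difference, but it is 1 array. The brightest Prm1 probe set differed by -0.077 while the others rose, so a candidate explanation is a piece of Prm1 sequence in the targeted allele, as protamine sequences are used in some constructs. The sequence of the allele would be needed to test this.

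Atrial genes were lower in knockout, and 2 other explanations were set against the genotype. Without knockout replicate 3 the mean difference was -0.11, short of both the value that less atrial tissue in that sample alone would need and the one that would count against it. The knockout array with high Xist had a list mean 0.031 above the wild-type mean, as a sex difference would have it, but this is 1 array. The fit with the Xist covariate makes the same comparison and adds nothing to it. How much atrium each sample held, sex and genotype cannot be told apart for this list.

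Myh7 and Tnni1 were higher in knockout within each replicate number, by 1.23, 1.39 and 2.12 for Myh7 and by 1.33, 0.53 and 0.69 for Tnni1. A hypothesis is that the knockout heart may be less mature. With the replicate block, 25 genes known to be high in the newborn heart had a mean difference of 0.038 and 19 genes high in the adult heart 0.0025, and the difference between the lists was 0.035 ± 0.069 (SE over 3 pairs). The fry p-values, unadjusted and from limma, were 0.594 and 0.953. A broad shift in maturity was thus not seen, and its absence was not shown either. The pair of replicate 2, whose arrays both had high Xist, differed by 1.39 for Myh7, which goes against sex as the whole cause but is 1 pair. The genotype stays open as the biological explanation.

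The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. Without the block the real split gave 0 genes and the highest of the others 4; any of the 10 gives at least 0, so this count says nothing. For probe sets the real split gave 3 and the highest of the others 18, and 2 of the 10 splits gave as many. For gene lists the real split gave 4 and the highest of the others 18, and 8 of the 10 gave as many. The 3 other splits that part every pair gave 0 probe sets and between 1 and 7 lists. The 4 splits that put the first replicates together gave 10 to 18 lists and the others 1 to 8, which points to a structure of the arrays, though the one with 18 lists also puts the low-Xist arrays together. The split with 18 probe sets is among these 4, and the other 3 gave 0 probe sets. With the replicate block, 4 splits part every pair. The real one gave 13 genes and the highest of the others 0, so 1 of the 4 gave as many, again too few for a share under 0.05.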
